A study of Drosophila melanogaster with 88 samples.

How the data were processed

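Fly RNA was profiled by sequencing the 3′ ends of polyadenylated transcripts, so most reads of a gene fall near its 3′ end and the value of a gene does not grow with its length. Per the labels, RNA was extracted by hand with phenol and chloroform, male libraries were made with a version 2 3′ mRNA kit with unique dual indices, and female libraries with the QuantSeq 3′ forward kit. The genome build named in the submitters' processing notes is dm6. The aligner, the counting program and the annotation release are not given in the sources used here, nor is whether duplicates or molecular identifiers were used.

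For males the authors deposited raw counts per feature, as whole numbers and not normalized, for 23996 features in 56 libraries. Of these features 17830 are genes, 5571 are single transposable element insertions, 114 are spike-in sequences and 481 are other entries. Gene features alone entered library sizes and tests. Insertions took 0.1695% to 0.2596% of the reads of a library, spike-ins at most 0.0001394%, and the other entries 0%. For females the deposited tables are named as CPM (counts per 1000000 reads) but hold log2 values, with a floor for unread genes that is constant within a table (-0.49 in heads and -1.34 in guts). These deposited log2 values were turned back into CPM by raising 2 to the value and subtracting 2 raised to the floor. The CPM steps then gave whole reads within 0.1 read for 100% of 284931 values, so the depth of each female library is known. The head and gut tables were normalized separately by the authors, and tests stayed within a table.

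Gene identifiers of 17751 male and 17251 female entries were found in the Ensembl annotation of the BDGP6 assembly, whose chromosome coordinates are those of dm6, and symbols and positions were taken from it. Reads shared between near-identical copies, such as members of the Turandot, Hsp70, cecropin, attacin, lysozyme and amylase families, may be split between copies by the counting, and values of single members are uncertain for that reason.

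Depth on genes came to at least 2.48 M reads per library in the 24 male libraries of the genotype series (median 7.11 M), 1.21 to 15 M in the 32 male libraries of the kay series (median 5.79 M), 0.201 to 6.82 M in the 16 female heads (median 3.13 M) and 0.937 to 9.46 M in the 16 female guts (median 4.85 M). A count of 0 allows a level of up to 0.182 to 1.21 CPM, 0.2 to 2.49 CPM, 0.44 to 15 CPM and 0.317 to 3.2 CPM in those tables, taking 3 reads as the limit. Such limits cover counting error only, since amplified reads are not independent molecules.

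Groups were taken from the labels: sex, tissue, genotype and age gave 22 groups of 4 libraries. The labels do not say that the 4 libraries of a group came from separate cultures, vials or sets of animals, so p-values measure the spread between these samples, which may be technical. No 2 libraries of a group matched within sampling noise. All columns were matched to a sample, and 0 were left unused.

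The comparisons, the test of each, the gene lists, the rule for the genes named and most alternative settings were chosen before the data were examined. Male counts were tested with edgeR 4.0.16 (quasi-likelihood test, TMM normalization, filterByExpr) under R 4.3.3, with 1 mean per group and 1 shared estimate of the spread over the 24 genotype libraries (9741 genes tested) or the 32 kay libraries (9796 genes). Standard errors for edgeR fold changes were computed as the absolute log2 fold change divided by the square root of the F statistic. Female values were tested with limma 3.58.1 (empirical Bayes with a trend) on log2(CPM + 1), for genes with at least 1 CPM in at least 4 libraries (9640 in heads and 9036 in guts), which understates the fold change of low genes. The plan had assumed plain CPM values. Adjusted p-values are Benjamini-Hochberg values over the genes tested, and a gene was called at an adjusted p under 0.05.

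The 38 gene lists, 31 of them used in heads and 35 in guts, cover innate immune and stress pathways, protein and energy metabolism, the circadian clock, genes linked to VAP and to ALS, and markers of the cell types that a head or a gut can hold. All but 1 of the names on them were matched. The list called yolk genes below holds yolk and ovary markers, eggshell genes among them. In heads and guts, changes on it were not separated from differences in ovary material carried into the samples. Lists with at least 2 tested members were tested with camera in limma at a preset correlation of 0.01 between genes, on log2 CPM with a prior count of 2 for males, with Benjamini-Hochberg adjustment over the lists of a comparison. The same test with a correlation estimated from the residuals, and fry, were run beside it. For each list the members past the threshold over all genes tested, and past it when adjusted over the list alone, were counted.

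In each comparison of P58S with WT or of a kay arm with its driver control, the rule named Vap33, kay, Jra, repo and w, the 6 largest rises and 6 largest falls among called genes whose groups did not overlap and whose mean was at least 10 CPM, and up to 3 members with the smallest p of each list that passed camera and of the antimicrobial peptide, JNK and ER stress lists in any case. For interactions, ages and the comparison of both overexpression arms it named the 3 largest rises and falls with a mean of at least 10 CPM and up to 2 members of lists that passed.

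All steps were tested on simulated counts with 200 genes changed by a known factor. For P58S against WT at day 5, the share recovered in the right direction at changes of 1.5, 2 and 4 fold was 18.5%, 61.5% and 88% in male heads, 0%, 2% and 27.5% in female heads, and 0%, 11% and 56.5% in female guts. For the kay knockdown against its driver control at day 5 it was 6%, 40.5% and 72%. A low count in females is therefore partly a limit of depth and spread.

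Alternatives planned for male counts were DESeq2 1.42.0, size factors of another kind in place of TMM, no filter on low counts, the replicate number as a block, and a fit on the compared groups alone. For females they were pseudocounts of 0.25 and 4 in place of 1, no filter on low values, median-centred libraries, the block and the compared groups alone. Each library was left out in turn. Chosen after seeing the data were the deposited log2 values as they are, edgeR on the recovered reads, female heads without the 2 shallowest WT day 5 libraries, and the library mean of the muscle marker list as a covariate in the kay series.

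Comparisons of the kay arms share 4 control libraries per age, so unchanged groups were simulated 20 times against the same controls, and the controls were also split 2 and 2 in all 6 ways. Overlaps between independent sets of libraries were tested with Fisher's exact test.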

Results

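The data are 88 fly libraries in 22 groups of 4. Male heads carrying wild-type VAP (WT) or VAP with the P58S change were profiled at 5, 15 and 20 days of age (24 libraries, median 7.11 M reads on genes, lowest 2.48 M). P58S is the fly counterpart of a VAPB change that causes a familial form of ALS in people. Female heads and guts of the same genotypes were profiled at days 5 and 20 (16 libraries each, 0.201 to 6.82 M and 0.937 to 9.46 M reads). In a second set of 32 male head libraries, at days 5 and 15, P58S flies carry the glial driver Repo alone (the driver control) or drive a kay knockdown (KayKD), kay overexpression (KayWT) or an overexpression arm labelled KaySCR (1.21 to 15 M reads). KaySCR is called overexpression in the deposited design text, and its construct is not described in the sources used here. Comparisons of P58S with WT ask what the change does to gene activity at each age and in each tissue. Those of the kay arms ask what altering the Fos transcription factor in glia does in P58S heads. The interactions ask whether either effect differs between ages. Fold changes are log2 values followed by their standard error (SE), CPM values are means with the SD of 4 libraries, and p-values are adjusted unless called unadjusted. For lists, the first p is from camera at its preset correlation and a second is given with an estimated correlation.

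In male heads at day 5, to (takeout, a secreted protein under clock control linked to feeding; dm6 chromosome 3R, 25240180 to 25241668) stood at 0.603 CPM (SD 0.218) in P58S and 23.8 CPM (SD 11.2) in WT, a fall of log2 -5.09 (SE 0.41, edgeR p 1.7e-08). Cyp6a14, a P450 enzyme gene (2R, 8564187 to 8567202), fell by -3.58 (SE 0.3, p 2.66e-08), and hbn, a homeobox transcription factor gene, by -2.16 (SE 0.22, p 8.28e-07). The gene t (tan), for a hydrolase that recycles histamine in photoreceptors, fell by -1.55 (SE 0.21, p 3.48e-05). Syt7, a calcium sensor of vesicle release (chromosome 4, 278685 to 306481), rose by 1.43 (SE 0.13, p 9.05e-08), from 78.6 CPM (SD 12.8) to 213 CPM (SD 58.1). CG42367 rose by 1.63 (SE 0.19, p 5.62e-06), CG34155 by 1.57 (SE 0.17, p 1.26e-06), CG9759 by 1.14 (SE 0.13, p 4.4e-06) and the P450 gene Cyp6w1 by 0.76 (SE 0.09, p 5.62e-06). Cyp6a2 was at 0 in all P58S libraries and at 3.39 CPM (SD 1.99) in WT.

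Vap33, which carries the change (X, 3948975 to 3955442), had a value of 0.17 (SE 0.065, p 0.188) at day 5. That of kay (3R, 29765995 to 29794113) was 0.34 (SE 0.1, p 0.0765; p 0.0306 without P58S replicate 1). Jra stood at -0.68 (SE 0.22, p 0.114; p 0.0483 without WT replicate 2), w -0.19 (p 0.891) and the glial gene repo -0.078 (p 0.9). Neuronal genes were higher as a list (19 tested, median 0.16, camera p 0.000708, 0.216 with an estimated correlation), with 1 past the threshold over all genes and 8 adjusted over the list alone. Glycolysis genes were lower (12 tested, median -0.2, p 0.00441, 0.0922 with an estimated correlation; 2 fell, 6 adjusted over the list alone). So was the list of selected P450 and detoxification genes (15 tested, median -0.24, p 0.00341, 0.0922 estimated; 1 rose and 2 fell, 1 and 5 over the list alone). The P450 genes Cyp4e3 (0.85) and Cyp12a4 (1.1), which rose, are outside that list. Fat body genes were lower (7 tested, median -0.46, p 0.00202, 0.0922 with an estimated correlation; 1 fell). So were ribosomal protein genes by a small step (81 tested, median -0.11, p 5.58e-05, 0.783 with an estimated correlation; 2 fell, among them RpS12 by -0.41, SE 0.071, p 0.00148). Antimicrobial peptide genes had a median of 0.86 (14 tested, p 0.0459, 0.898 with an estimated correlation; 0 passed), with DptA at 1.85 (SE 0.85, p 0.267) and AttB at 1.18 (SE 0.45, p 0.165). WT replicate 1 stood apart on this list (mean log2 CPM 3.14, others 4.82 to 5.07), in the direction of a higher P58S value. The Imd pathway list had a median of 0.18 (21 tested, p 0.0251, 0.0922 with an estimated correlation; 0 passed, 2 higher over the list alone). Camera p-values were 0.447 for the JNK pathway (16 tested, 0 passed), 0.909 for JNK target genes (11 tested, 0 passed), 0.991 for ER stress genes (22 tested, 0 passed) and 0.194 for orthologues of ALS genes (16 tested). In all, 82 genes rose and 109 fell of 9741 tested with edgeR. That count was 116, 120 or 91 without WT replicate 2, 3 or 4 and 365 without P58S replicate 1. Of 35 ways of splitting the 8 libraries 4 and 4, 1 other gave 211 genes, so chance cannot be excluded for this count.

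At day 15, to was again far lower in P58S, at -3.99 (SE 0.37, p 1.84e-07), and Rh5, the blue-sensitive opsin (2L, 12008153 to 12009832), fell by -2.67 (SE 0.17, p 4.8e-11), from 61.2 CPM (SD 5.91) to 9.32 CPM (SD 1.55). The clock genes tim (2L, 3493986 to 3508119) and vri (2L, 5288944 to 5311223) fell by -1.48 (SE 0.21, p 9.63e-05) and -1.23 (SE 0.15, p 7.82e-06). In addition hbn fell by -1.33 (SE 0.22, p 0.00063) and CG9150 by -1.72 (SE 0.27, p 0.000412). Cyp4e3, a P450 gene (2L, 9747839 to 9750071), rose by 1.7 (SE 0.22, p 4.27e-05), from 22.9 CPM (SD 6.24) to 73.4 CPM (SD 9.03). CG34180 rose by 2.29 (SE 0.29, p 2.41e-05), CG42367 by 1.79 (SE 0.19, p 1.92e-06) and the mitochondrial P450 gene Cyp12a4 by 1.61 (SE 0.27, p 0.001). The clock list was lower (8 tested, median -0.3, p 4.22e-05, 0.012 with an estimated correlation; 2 fell, 1 higher and 5 lower over the list alone).

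Antimicrobial peptide genes were higher as a list at day 15 (14 tested, median 1.09, p 1.32e-09, 0.197 with an estimated correlation), though 0 passed singly. Mtk stood at 1390 CPM (SD 600) against 372 CPM (SD 399), a value of 1.87 (SE 0.6, p 0.181; p 0.0117 without WT replicate 2), and Dro at 1.92 (SE 0.74, p 0.349; p 0.00287 without WT replicate 2). Bomanins, short peptides made downstream of Toll, had a median of 0.3 (15 tested, p 9.18e-07, 0.187 with an estimated correlation; 0 passed, 4 over the list alone). Turandot stress genes were higher (4 tested, median 1.41, p 8.85e-05, 0.187 with an estimated correlation; 1 rose, 3 over the list alone). Photoreceptor genes were lower (21 tested, median -0.043, p 0.0302, 0.197 estimated; 2 fell, 1 higher and 4 lower over the list alone), and yolk genes were lower (3 tested, median -1.14, p 0.0289, 0.187 estimated; 0 passed, 1 over the list alone). At this age kay had a value of 0.23 (SE 0.1, p 0.483) and Vap33 0.14 (SE 0.065, p 0.549). Camera p-values were 0.926 for the JNK pathway, 0.545 for JNK targets and 0.668 for ER stress genes. In all, 47 genes rose and 52 fell (edgeR), and the 34 other splits of these libraries gave at most 1.

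By day 20, to was at 0.653 CPM (SD 0.241) in P58S and 47.2 CPM (SD 10.6) in WT, -6.35 (SE 0.44, p 3.03e-10). Rh5 fell by -2.81 (SE 0.17, p 3.48e-11). Cyp6a14 fell by -2.98 (SE 0.3, p 4.59e-07), CG10560 by -2.27 (SE 0.24, p 1.33e-06), t by -1.9 (SE 0.22, p 4.42e-06) and the transporter gene Mrp5 by -1.31 (SE 0.18). Cyp4e3 rose by 2.54 (SE 0.23, p 6.33e-08), from 21.2 CPM (SD 1.48) to 119 CPM (SD 29.2), and Cyp12a4 by 1.67 (SE 0.27, p 0.000373). Hr38, a nuclear receptor gene induced by neuronal activity (2L, 20683462 to 20714588), rose by 1.56 (SE 0.21, p 3.57e-05). The clock genes now moved the other way: vri rose by 1.11 (SE 0.15, p 3.86e-05) and tim by 1.08 (SE 0.21, p 0.00343). The clock list was higher (8 tested, median 0.32, p 0.0078, 0.053 with an estimated correlation; 2 rose and 1 fell, 5 and 1 over the list alone).

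Bomanins were higher as a list at day 20 (15 tested, median 0.49, p 4.44e-11, 0.053 with an estimated correlation; 4 rose, 12 over the list alone). Among the single genes BomS5 rose by 0.84 (SE 0.16, p 0.00236), BomS3 by 0.69 (SE 0.13, p 0.00205) and Dso2 by 0.7 (SE 0.13, p 0.00161; 1180 CPM, SD 71, against 745 CPM, SD 67.2). Antimicrobial peptide genes were higher as a list (14 tested, median 1.42, p 4.24e-05, 0.296 with an estimated correlation; 1 rose), with Dro at 2.03 (SE 0.73, p 0.208) and Mtk at 1.61 (SE 0.59, p 0.217). JNK targets were higher too (11 tested, median 0.14, p 0.00311, 0.0508 with an estimated correlation; 1 rose, 5 over the list alone). Among them Mmp1, a matrix metalloproteinase induced by JNK, rose by 0.86 (SE 0.15, p 0.00131), and puc had a value of 0.4 (SE 0.11, p 0.0653). Camera also gave p 0.0341 for the JNK pathway (16 tested, median 0.053, 0.0707 with an estimated correlation; 0 passed, 2 over the list alone) and 0.0297 for JAK-STAT genes (7 tested, median 0.23, 0.0707 estimated; 0 passed).

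Turandot genes were higher at day 20 (4 tested, median 2.15, p 0.00158, 0.111 with an estimated correlation; 2 rose, 3 over the list alone). So were muscle genes (12 tested, median 0.25, p 4.24e-05, 0.053 with an estimated correlation; 2 rose, among them TpnC41C by 0.82, SE 0.15, p 0.00154). The P450 list, which leaves out Cyp4e3 and Cyp12a4, was lower (15 tested, median -0.18, p 0.000158, 0.0508 with an estimated correlation; 3 fell, 1 higher and 4 lower over the list alone). So were oxidative phosphorylation genes (40 tested, median -0.089, p 0.0105, 0.296 estimated; 0 passed) and fat body genes (7 tested, median -0.24, p 0.00877, 0.0847 estimated; 1 rose and 1 fell). ER stress genes gave p 0.297 (22 tested), and Thor, a translation repressor on that list, rose by 0.62 (p 0.000101). At this age kay had a value of 0.35 (SE 0.1, p 0.0853; p 0.0424 without WT replicate 4 and 0.0362 without P58S replicate 4). Vap33 stood at 0.22 (SE 0.065, p 0.0982). In all, 84 genes rose and 87 fell (edgeR). That count was 107 without WT replicate 3 and 108 without P58S replicate 4. Other splits of these libraries gave at most 50.

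**Figure D1:**
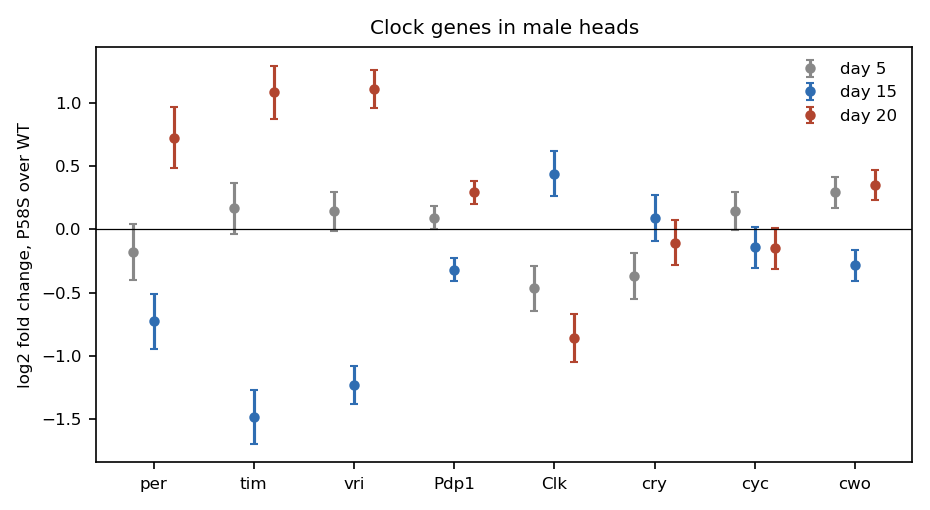
Log2 fold change, P58S against WT, with SE, of 8 clock genes in male heads at days 5, 15 and 20, 4 libraries per group.

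**Figure D2:**
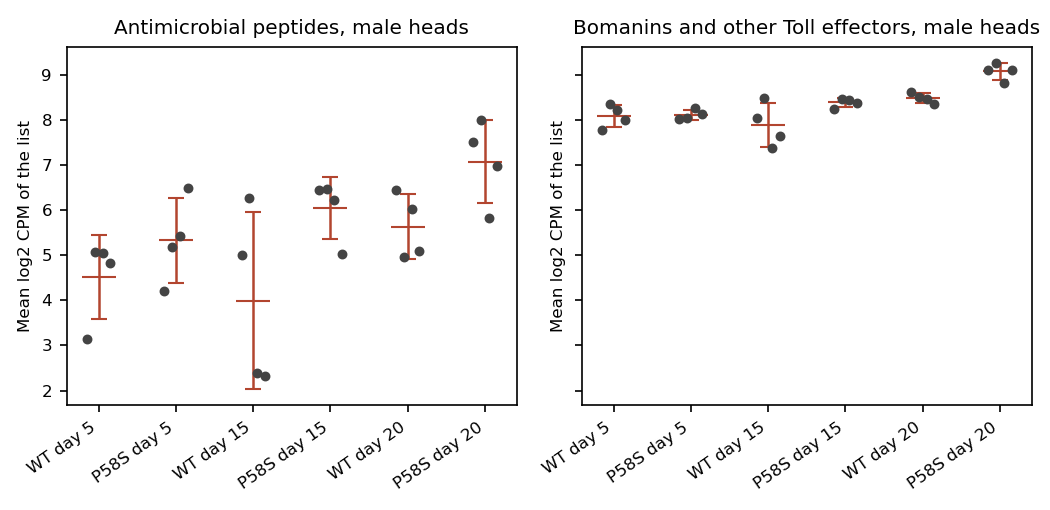
Mean log2 CPM of the antimicrobial peptide list and of the Bomanin list in each male head library, for WT and P58S at days 5, 15 and 20. Points are libraries and bars are the mean with SD of 4; Bomanins stood at 9.07 (SD 0.181) in P58S and 8.48 (SD 0.112) in WT at day 20.

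A set of 31 genes was called in the same direction at all 3 male ages, 14 higher and 17 lower in P58S. Syt7 (0.89 at day 15 and 1.08 at day 20), Cyp4e3, Cyp12a4, jeb and the insulin-like peptide gene Ilp7 are among those higher, and to, Rh5, t, Cyp6a14, Cyp6a2, RpS12 and Pgi among those lower. By chromosome they lie on 2L (8 genes), 2R (6), 3L (6), 3R (8), 4 (1) and X (2). Of the 29 also tested in female heads, 21 had the same sign at day 5 (13 of 13 higher and 8 of 16 lower, binomial p 0.0241) and 20 at day 20 (8 and 12, p 0.0614). The median over all female head genes was 0.647 at day 5. Relative to the all-gene median, chosen after seeing the data, 20 had the same sign at day 5 (8 and 12, p 0.0614) and 18 at day 20 (6 and 12, p 0.265). These values come from different kits as well as the other sex. In female guts 18 were tested, with 15 of the same sign at day 5 and 13 at day 20.

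**Figure D3:**
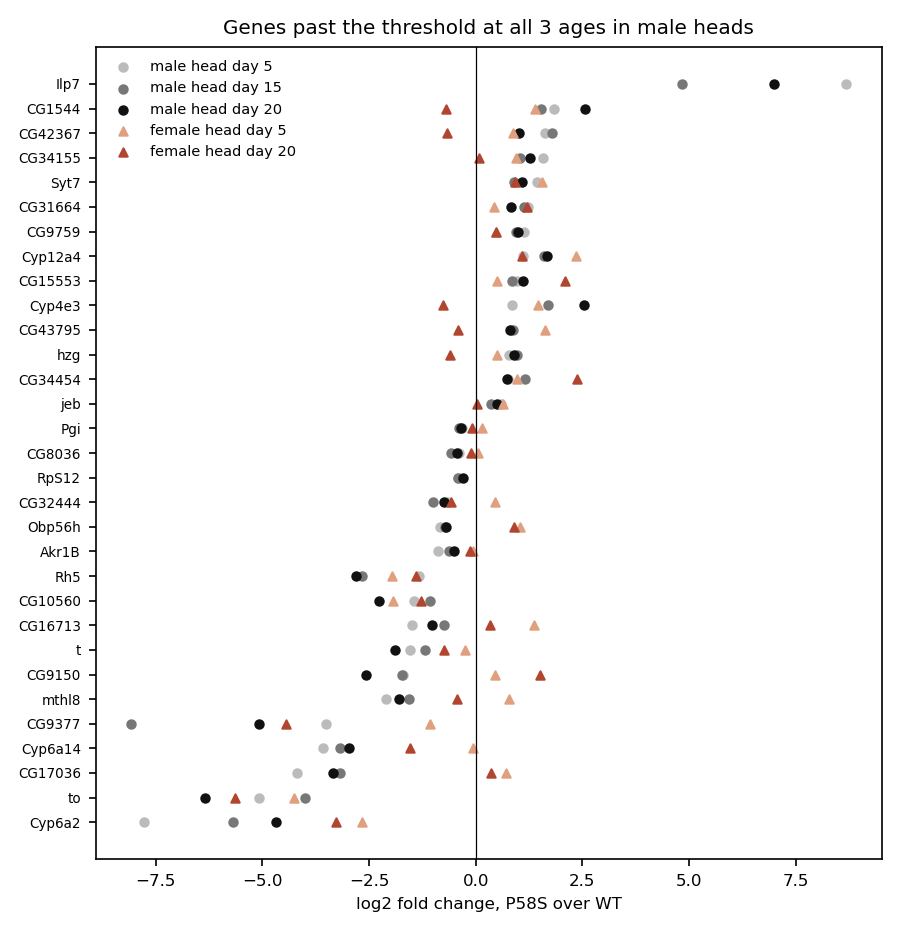
Log2 fold change, P58S against WT, of the 31 genes at the 3 male ages (circles) and at the 2 female head ages (triangles, log2(CPM + 1) values without rescaling), 4 libraries per group. Fitted values of genes with a group near 0, such as Ilp7, depend on the fit.

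The effect of P58S differed between days 15 and 5 for few genes: the lactate dehydrogenase gene Ldh (1.57, SE 0.21, p 0.000626) and CG7203 (1.87, SE 0.3, p 0.00502) rose relative to WT with age. Falls were seen in tim (-1.65, SE 0.29, p 0.00746), vri (-1.37, SE 0.21, p 0.00211) and Rh5 (-1.35, SE 0.23, p 0.00746). Between days 20 and 5, Hr38 (2.05, SE 0.29, p 0.000857) and the odorant-binding protein gene Obp56e (1.87, SE 0.28, p 0.00178) rose relative to WT. In contrast CG8620 (-1.92, SE 0.34, p 0.00935) and Rh5 (-1.5, SE 0.24, p 0.00297) fell. Bomanins gained on WT with age, by a median of 0.34 to day 15 (p 0.000944, 0.399 with an estimated correlation) and 0.53 to day 20 (p 1.85e-06, 0.263 with an estimated correlation; 0 passed, 4 over the list alone). Turandot genes did so by 2.28 (p 0.000456, 0.126 estimated; 3 over the list alone) and 3.02 (p 0.00336, 0.263 estimated; 3 over the list alone). TotA stood at 2.31 (SE 0.51, p 0.0553) to day 20, passing without WT day 5 replicate 1 (p 0.0445), P58S day 5 replicate 3 (p 0.0285) or P58S day 20 replicate 2 (p 0.0202). Antimicrobial peptide genes had a median of 0.42 to day 15 (p 0.0129, 0.635 with an estimated correlation).

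To day 15 the clock list was lower relative to WT (median -0.48, p 0.000944, 0.0507 with an estimated correlation; 2 fell). So were photoreceptor genes (-0.13, p 0.00555, 0.126 estimated; 1 fell). Oxidative phosphorylation (median 0.12, p 0.00528, 0.399 with an estimated correlation), glycolysis (p 0.00528, 0.12 estimated; 1 rose, 2 over the list alone), ribosomal protein (p 0.00964, 0.729 estimated) and fat body genes (p 0.0129, 0.172 estimated; 1 rose) were higher. To day 20 JNK targets (median 0.33, p 0.014, 0.13 with an estimated correlation; 0 passed, 2 over the list alone) and muscle genes (0.28, p 0.00691, 0.263 estimated; 0 passed, 2 over the list alone) were higher. In all, 6 genes rose and 4 fell to day 15 (edgeR). That count was 18 without WT day 5 replicate 1 and 6 without WT day 15 replicate 1 or 3. To day 20, 15 rose and 5 fell. Their count was 10 without WT day 5 replicate 2, and 8 without WT day 5 replicate 4. It was 11, 10, 10 or 12 without WT day 20 replicates 1 to 4, and 10 or 11 without P58S day 20 replicate 1 or 2. Of 60 exchanges of libraries, 5 others gave at least 20 genes to day 20 (the highest gave 70), so chance cannot be excluded there. To day 15 the highest gave 5.

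In WT male heads between days 5 and 20, the fatty acid synthase gene FASN1 rose by 0.91 (SE 0.1, p 1.64e-06; 336 CPM, SD 25.9, to 664 CPM, SD 49) and the lipase gene bmm by 0.88 (SE 0.14, p 0.000147). The synaptic calcium sensor gene Syt1 fell by -0.63 (SE 0.08, p 6.5e-06). So did the muscle genes Mhc (-0.64, SE 0.091, p 3.33e-05) and bt (-0.61, SE 0.082, p 1.27e-05). CG11458 fell from 264 CPM (SD 53.4) to 0.839 CPM (-8.42, SE 0.61, p 4.01e-10) and Scp1 by -3 (SE 0.26, p 1.21e-08). CG8620 rose by 4.28 (SE 0.25, p 1.45e-11), CG12256 by 3 (SE 0.2, p 1.2e-10) and the stress gene Gadd45 by 2.19 (SE 0.25, p 1.64e-06). Neuronal genes fell as a list (19 tested, 10 fell, 14 over the list alone, median -0.41, p 2.36e-10, 0.0216 with an estimated correlation). Lipid genes rose (19 tested, 9 rose, 10 over the list alone, 0.44, p 5.41e-06, 0.0293 estimated) and proteasome genes rose (30 tested, 5 rose, 8 over the list alone, 0.25, p 7.86e-06, 0.00441 estimated).

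Ribosomal protein genes were higher with WT age (81 tested, 23 rose, 36 over the list alone, median 0.25, p 1.31e-12, 0.183 with an estimated correlation). Oxidative phosphorylation genes were lower (40 tested, 11 fell, 17 over the list alone, -0.24, p 1.34e-07, 0.0631 estimated; ATPsynB -0.6, SE 0.094, p 0.000109). So were muscle genes (12 tested, 5 fell, 6 over the list alone, -0.42, p 5.25e-05, 0.069 estimated). Immune lists were higher: Bomanins (3 rose, 5 over the list alone, p 0.00317, 0.27 with an estimated correlation), antimicrobial peptides (2 rose, p 0.0377, 0.588 estimated) and Imd genes (4 rose, p 0.0436, 0.111 estimated), with Dso1 up by 0.78 (SE 0.17, p 0.00296). Higher too were neuropeptide genes (27 tested, 8 rose and 2 fell, p 0.0436, 0.183 with an estimated correlation, Orcokinin 0.81, SE 0.13, p 0.000179) and genes of apoptosis and Xrp1 (2 rose, p 0.0492, 0.183 estimated; Irbp18 0.72, p 0.00153). Glial genes were lower (14 tested, 1 rose and 4 fell, p 0.0292, 0.111 estimated; nrv2 -0.74, SE 0.11, p 3.33e-05). In all, 494 genes rose and 537 fell (edgeR).

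In female heads at day 5 the median change over all genes was 0.647, so changes are also given relative to that shift. WT libraries held 0.201 to 3.65 M reads and 4043 to 9738 detected genes, and P58S libraries 3.1 to 3.69 M and 9272 to 9607. Shallow WT libraries can lower the WT values of low genes, so 1 shift may not suit well-read genes. Rh4, the ultraviolet-sensitive opsin (3L, 16852527 to 16862517), fell by -5.14 (SE 0.83, limma p 0.0331; -5.82 relative to the median, p 0.000102). The gene to fell by -4.27 (SE 0.8, p 0.0493; -4.95 relative, p 0.00313) and CG34215 by -2.41 (SE 0.45, p 0.0493; -3.1 relative, p 0.0228). The antimicrobial peptide gene AttC rose by 3.87 (SE 0.71, p 0.0493; 3.19 relative, p 0.0323), from 1.19 CPM (SD 1.97) to 28.6 CPM (SD 16.3). Genes of the yolk and ovary list, eggshell genes among them, were lower (12 tested, median -1.88, camera p 8.58e-08, 0.169 with an estimated correlation, 0 passed, 2 over the list alone). Ribosomal protein genes were lower relative to the rest (77 tested, median -0.017, camera p 2.93e-06, 0.373 estimated, 0 passed). Oxidative phosphorylation genes passed as lower although their median is positive (40 tested, median 0.027, p 0.0461, 0.506 with an estimated correlation; 0 passed), since camera compares them with the other genes. Values of kay (-0.061, SE 0.27), Vap33 (0.19, SE 0.17, p 0.562), repo (0.99, SE 0.9), Jra (0.41, SE 1) and w (1.95, p 0.297) did not pass. Nor did the JNK pathway (p 0.375), JNK targets (p 0.784) or ER stress genes (p 0.841). In all, 1 gene rose and 4 fell of 9640, and every call is lost in some fit with 1 library left out. Lost without WT replicate 3 are AttC, Rh4, to and CG34215 (each p 0.0744), and without WT replicate 4 AttC and to (p 0.171) and CG34215 (p 0.0796). Without P58S replicates 1 to 4 the p-values of AttC are 0.0599, 0.152, 0.216 and 0.255 and those of CG34215 0.224, 0.152, 0.145 and 0.255. For Rh4 they are 0.0904, 0.0728 and 0.139 without P58S replicates 1 to 3, and for to 0.224, 0.139 and 0.255 without 1, 3 and 4. The counts were 384, 12, 0 and 2 without WT replicates 1 to 4 and 0, 1, 0 and 1 without P58S replicates 1 to 4, in a group where WT depth ran from 0.201 to 3.65 M reads.

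At day 20 Rh4 (246 CPM, SD 47.9, in WT and 2.34 CPM in P58S; -6.21, SE 0.83, p 0.00194) and to (-5.63, SE 0.8, p 0.00232) fell in female heads in every fit with 1 library left out. CG6006, a transporter-like gene, fell by -2.06 (SE 0.34, p 0.0145; -2.26 relative to an all-gene median of 0.159, p 0.0468). That call is lost without WT replicate 1, 2 or 3 (p 0.0672, 0.0528, 0.0861) or P58S replicate 1 or 3 (p 0.109, 0.0725). Bomanins were higher as a list (15 tested, median 1.1, p 2.13e-10, 0.108 with an estimated correlation; 0 passed, 10 over the list alone), with BomS5 at 1.32 (SE 0.27, p 0.0871; p 0.0181 without P58S replicate 2). Antimicrobial peptides (14 tested, 1.72, p 2.4e-07, 0.194 with an estimated correlation; 0 passed), Turandot genes (4 tested, 2.14, p 0.00221, 0.159 estimated; 0 passed, 2 over the list alone) and heat shock genes (16 tested, 1.16, p 0.00093, 0.755 estimated; 0 passed) were higher. Ribosomal protein genes were lower (-0.11, p 2.71e-05, 0.546 with an estimated correlation). Here kay had a value of 0.38 (SE 0.27, p 1) and Vap33 0.018 (SE 0.17, p 1). Camera p-values were 0.764 for the JNK pathway, 0.208 for JNK targets (median 0.55) and 0.819 for ER stress genes. In all 3 genes fell and 0 rose (limma), 5 without P58S replicate 2.

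In female heads the P58S effect on Bomanins was higher at day 20 relative to day 5 by a median of 0.8 (p 1.24e-06, 0.206 with an estimated correlation; 3 over the list alone), with an all-gene median of -0.385. Yolk genes were also higher (1.43, p 3.07e-05, 0.206 with an estimated correlation). So were heat shock genes (1.16, p 0.000792, 0.822 estimated). Neuronal genes were lower (-0.61, p 0.0445, 0.822 estimated) and muscle genes were higher (0.48, p 0.0159, 0.206 estimated). For single genes limma gave 0 past the threshold (523 at an unadjusted p under 0.05) and edgeR on the recovered reads gave 0. With 0 genes called, exchanges of libraries cannot test for chance.

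With age in WT female heads AttC rose by 5.29 (SE 0.71, p 0.000415; 4.86 relative to an all-gene median of 0.346), Mtk by 3.23 (SE 0.63, p 0.0106) and the stress gene TotC by 4.49 (SE 0.74). CG11458 fell by -7.77 (SE 0.59, p 6.88e-08), as in males. The eggshell genes Vm26Ab (-6.17), Vm26Aa (-6.13) and Vm34Ca (-5.51) fell. Muscle genes fell (12 tested, 3 fell, 9 over the list alone, p 1.83e-07, 0.0102 with an estimated correlation; Mlc2 -1.13, SE 0.18, p 0.00175; day 20 replicate 1 at 6.02 mean log2 CPM, others 6.64 to 6.7). Yolk genes fell too (12 tested, 5 fell, p 1.22e-09, 0.0423 estimated). Antimicrobial peptides were higher (14 tested, 3 rose, 6 over the list alone, p 0.00327, 0.488 with an estimated correlation). So were Turandot genes (4 tested, 2 rose, p 0.00153, 0.0833 estimated). The same holds for Toll genes (19 tested, p 0.0245, 0.552 estimated), lipid genes (2 rose, 5 over the list alone, p 0.037, 0.488 estimated) and ribosomal protein genes (77 tested, 9 rose, 38 over the list alone, p 0.00329, 0.552 estimated). Heat shock genes (-1.26, p 2.87e-05, 0.43 with an estimated correlation) and oxidative phosphorylation genes (p 0.00169, 0.31 estimated) were lower. In all 57 genes rose and 37 fell (limma). That count was 460, 178 or 192 without WT day 5 replicate 1, 2 or 3 and 56 without WT day 20 replicate 4. Other splits gave up to 167 genes, so chance cannot be excluded.

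In female guts at day 5 the metallothionein gene MtnC (3R, 20360308 to 20360634) fell from 141 CPM (SD 18.2) in WT to 0.168 CPM in P58S (-6.93, SE 0.42, limma p 3.77e-10). The lysozyme gene LysX (3L, 1194739 to 1195302) rose from 0.918 CPM to 44.2 CPM (SD 26.1; 4.34, SE 0.56, p 0.000406). CG43055 rose by 1.72 (SE 0.25, p 0.00162), Cyp12a4 by 1.23 (SE 0.17, p 0.000716; 110 CPM, SD 8.4, to 259 CPM, SD 17.2), and CG6283 fell by -1.68 (SE 0.25, p 0.00162). Lysozymes rose as a list (6 tested, 1 rose, 5 over the list alone, median 0.59, p 6.9e-08, 0.0268 with an estimated correlation). Lower lists, all at 0.923 with an estimated correlation, were Bomanins (-0.38, p 0.0323), ER stress (21 tested, -0.23, p 0.0352; 0 passed), glycolysis (p 0.0352), lipid (p 0.038) and proteasome genes (p 0.0255). Carbohydrate digestion (0.26, p 0.045; 1 over the list alone) and ribosomal protein genes (0.076, p 0.018) were higher, again at 0.923 with an estimated correlation. Fat body genes were lower (7 tested, 1 fell, 2 over the list alone, p 0.018, 0.439 estimated). Values were 0.22 for kay (SE 0.35, p 1) and 0.12 for Vap33 (SE 0.16, p 1). The list tests gave p 0.763 for the JNK pathway and 0.807 for JNK targets. In all, 7 genes rose and 5 fell of 9036. That count was 6 without WT replicate 2, 5 without P58S replicate 1 and 7 without P58S replicate 4.

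At day 20 in guts MtnC (285 CPM, SD 135, in WT and 1.62 CPM in P58S; -6.87, SE 0.42, p 4.55e-10) and LysX (5.09, SE 0.56, p 2.55e-05) kept these changes. So did CG43055 (1.56, SE 0.25, p 0.00326), and CG6295, a lipase-like gene, fell by -1.63 (p 0.00337). IFT57, of intraflagellar transport, fell by -2.99 (SE 0.48, p 0.00326), CG15254 by -2.21 (SE 0.33, p 0.00234) and CG34211 by -3.16 (SE 0.5, p 0.00289). The amylase genes Amy-p and Amy-d rose by 1.44 (SE 0.26, p 0.00963) and 1.07 (SE 0.19, p 0.00945), calls lost without WT replicate 1 (p 0.0563 for each). Carbohydrate digestion genes were higher (12 tested, 2 rose, 4 higher and 1 lower over the list alone, median 1, p 4.52e-06, 0.457 with an estimated correlation). So were antimicrobial peptides (12 tested, 1.02, p 4.9e-05, 0.457 estimated; P58S replicate 2 at 3.36 mean log2 CPM, others 2.83 to 2.9), Bomanins (0.57, p 4.9e-05, 0.744 estimated) and heat shock genes (0.67, p 0.00243, 0.973 estimated). Muscle genes were lower (-0.33, p 0.0221, 0.912 with an estimated correlation; 2 over the list alone). Here kay had a value of 0.5 (SE 0.35, p 0.743) and Vap33 -0.041 (p 0.969). Camera p-values were 0.48 for the JNK pathway, 0.838 for JNK targets and 0.987 for ER stress. They were 0.138 for intestinal stem cell and progenitor genes (median 0.32) and 0.391 for Malpighian tubule genes. In all, 12 genes rose and 21 fell (limma).

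In guts the P58S effect was higher at day 20 relative to day 5 for Bomanins (p 3.6e-07, 0.754 with an estimated correlation; -0.38 and 0.57 at days 5 and 20). The same holds for antimicrobial peptides (p 0.00422, 0.754 estimated; 0.31 and 1.02), heat shock genes (1.14, p 0.00439, 0.788 estimated; -0.15 and 0.67) and carbohydrate digestion genes (p 0.0167, 0.788 estimated). It was lower for oxidative phosphorylation genes (p 0.00513, 0.788 estimated). Single genes past the threshold came to 0 with limma (276 at an unadjusted p under 0.05) and 0 with edgeR on recovered reads, with 1 without WT day 5 replicate 3 or P58S day 20 replicate 2. Exchanges of libraries cannot test for chance here either.

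In ageing WT guts CG43055 rose by 1.97 (SE 0.25, p 0.000814). COX7AL2, a cytochrome oxidase subunit gene, fell by -3.28 (SE 0.54, p 0.00839), the chorion gene Cp15 by -3.48 (p 0.00645) and the protease gene Jon25Bi by -1.94 (SE 0.31, p 0.00645). Yolk genes were lower (12 tested, 1 fell, 10 over the list alone, median -1.87, p 3.54e-12, 0.14 with an estimated correlation). Enteroendocrine genes (1 rose, 4 over the list alone, p 6.17e-06, 0.178 estimated) and neuropeptide genes (1 rose, 4 over the list alone, p 0.00022, 0.178 estimated) were higher. Autophagy genes (0.49, p 0.00124, 0.534 with an estimated correlation) and enterocyte and copper cell genes (0.57, p 0.0107, 0.461 estimated) were higher. Heat shock (-0.87, p 0.000684, 0.71 estimated), digestive protease (26 tested, 2 fell, p 0.00247, 0.534 estimated), haemocyte (p 0.00491, 0.347 estimated) and Bomanin genes (p 0.0105, 0.809 estimated) were lower. Malpighian tubule genes gave p 0.121, and the testis list had 1 tested member and so no test. In all, 8 genes rose and 11 fell (limma). That count was 8 or 10 without WT day 5 replicate 2 or 4 and 7, 11, 11 or 49 without WT day 20 replicates 1 to 4.

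In whole heads at day 5 the kay level itself was 197 CPM (SD 10.7) in KayKD, 218 CPM (SD 18) in KayWT, 293 CPM (SD 30.1) in KaySCR and 207 CPM (SD 19.3) in the driver control. The fold changes were -0.059 (SE 0.12, p 0.833), 0.14 (SE 0.11, p 0.556) and 0.49 (SE 0.11, p 0.014). The last call is lost without driver replicate 3 (p 0.0613) or KaySCR replicate 4 (p 0.0599). Glia are a minority of head cells and 3′ tags may miss a transgene with its own 3′ end, so a change in glia alone can be hidden here. The transgene marker w had values of 0.28 in KayKD (p 0.643) and 1.06 in KayWT (SE 0.27, p 0.0137; p 0.0955 or 0.0503 without driver replicate 2 or 4). It was 1.18 in KaySCR (SE 0.27, p 0.0121; p 0.0843 without driver replicate 2). The glial gene repo had values of -0.44 (p 0.27), -0.37 (p 0.34) and -0.069 (p 0.918), and Vap33 of 0.041, 0.015 and 0.089, none passed.

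KayKD at day 5 raised the larval serum protein (hexamerin) genes Lsp1beta, from 189 CPM (SD 110) to 934 CPM (SD 116; 2.3, SE 0.34, p 6.64e-05) and Lsp1alpha by 4.09 (SE 0.88, p 0.00493). CG11313, a protease-like gene (3R, 30729837 to 30731165), stood at 40.4 CPM (SD 7.54) against 0 in the driver control (p 6.91e-08). Oxidative phosphorylation genes fell (40 tested, 15 fell, 26 over the list alone, median -0.34, p 3.42e-13, 0.0192 with an estimated correlation). The complex I gene ND-30 fell by -0.79 (SE 0.14, p 0.000895) and the complex IV gene COX6B by -0.65 (SE 0.12, p 0.00175). Muscle genes fell (12 tested, 4 fell, 6 over the list alone, -0.38, p 9.78e-05, 0.0192 with an estimated correlation; Act57B, 2R, 20944021 to 20946431, -0.59, SE 0.11, p 0.00133). KayKD replicate 4 was lowest on this list (6.8, others 7.16 to 7.21 mean log2 CPM). Ribosomal protein genes were lower (82 tested, 7 fell, 14 over the list alone, -0.13, p 9.78e-05, 0.813 estimated). The attacin gene AttA had a value of 2.47 (SE 0.75, p 0.0589, and 0.0405 without KayKD replicate 1). Camera p-values were 0.406 for the JNK pathway (0 passed), 0.859 for JNK targets (0 passed) and 0.672 for ER stress. In all, 173 genes rose and 178 fell of 9796 (edgeR). That count was 629, 191 or 172 without driver replicate 1, 2 or 3 and 225 without KayKD replicate 3.

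KayWT at day 5 raised the opsin gene Rh5 from 3.15 CPM (SD 1.83) to 25.4 CPM (SD 5.4; 3.13, SE 0.28, p 5.61e-09), CG34456 by 3.13 (SE 0.3, p 4.04e-08) and CG16926 by 2.22 (SE 0.29, p 8.86e-06). The largest rise, of S-Lap1 (5.79, SE 1.4, p 0.00973; 1.37 to 73.6 CPM), is lost without KayWT replicate 4 (p 0.31). That library had 12275 genes detected, the others 10331 to 11000. Syt1 fell from 1940 CPM (SD 580) to 774 CPM (SD 87.9; -1.28, SE 0.16, p 3.77e-06). The neuronal list was lower with it (19 tested, 5 fell, 9 over the list alone, median -0.25, p 2.92e-06, 0.331 with an estimated correlation). Muscle genes fell (12 tested, 4 fell, 9 over the list alone, -0.58, p 2.67e-07, 0.00295 with an estimated correlation; Act57B -0.77, SE 0.11, p 2.7e-05). Antimicrobial peptides were lower (15 tested, 4 fell, 7 over the list alone, -1.67, p 0.000334, 0.77 with an estimated correlation). CecA2 stood at 2.06 CPM against 56 CPM (-4.47, SE 1.1, p 0.0135; p 0.0585 without driver replicate 3 and 0.051 without KayWT replicate 2). Oxidative phosphorylation genes were lower (40 tested, 5 fell, 2 higher and 14 lower over the list alone, -0.24, p 2.92e-06, 0.331 with an estimated correlation). So were VAP-binding genes (9 tested, 2 fell, -0.24, p 0.0366, 0.331 estimated). Nrf2 genes were higher (17 tested, 1 rose, 0.3, p 0.0457, 0.331 estimated). P-values were 0.849 for the JNK pathway (0 passed), 0.874 for JNK targets (0 passed) and 0.72 for ER stress. In all, 295 genes rose and 253 fell (edgeR). That count was 1092, 253 or 285 without driver replicate 1, 2 or 3 and 308 or 384 without KayWT replicate 2 or 4.

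KaySCR at day 5 raised Rh5 to 41.4 CPM (SD 5.1; 3.76, SE 0.28, p 4.08e-11), CG11893 by 3.62 (SE 0.5, p 4.71e-05), fs(1)K10 by 2.16 (SE 0.34, p 0.000176) and the phototransduction channel gene trpl by 0.58 (SE 0.1, p 0.000664). The Bomanin gene BomBc1 fell from 211 CPM (SD 55.8) to 47.1 CPM (SD 7.97; -2.18, SE 0.33, p 0.000114). BomS4 fell by -0.81 (SE 0.17, p 0.00585), and Act57B by -0.88 (SE 0.11, p 9.94e-06). Muscle genes fell as a list (3 fell, 6 over the list alone, median -0.38, p 6.84e-06, 0.00969 with an estimated correlation). Antimicrobial peptides (15 tested, 1 fell, 5 over the list alone, -1.21, p 0.00118, 0.813 with an estimated correlation) and oxidative phosphorylation genes (4 fell, p 5.53e-05, 0.556 estimated) were lower. Photoreceptor genes were higher (21 tested, 4 rose, 7 over the list alone, p 0.0241, 0.719 estimated). Bomanins passed as lower (15 tested, 4 fell, 5 over the list alone, p 0.0196, 0.813 with an estimated correlation) with a median of 0.085 and a mean of -0.5, so the falls of a few members carry the test. P-values were 0.6 for the JNK pathway, 0.982 for JNK targets (0 passed) and 0.54 for ER stress (0 passed). In all, 131 genes rose and 124 fell (edgeR). That count was 690, 96 or 102 without driver replicate 1, 2 or 3 and 112, 132 or 131 without KaySCR replicate 1, 3 or 4. Another split gave 293 genes, so chance cannot be excluded, whereas for KayKD and KayWT the highest others gave 307 and 129. With the muscle list mean as a covariate, chosen after seeing the data, the day 5 counts were 80 for KayKD, 74 for KayWT and 61 for KaySCR.

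**Figure D4:**
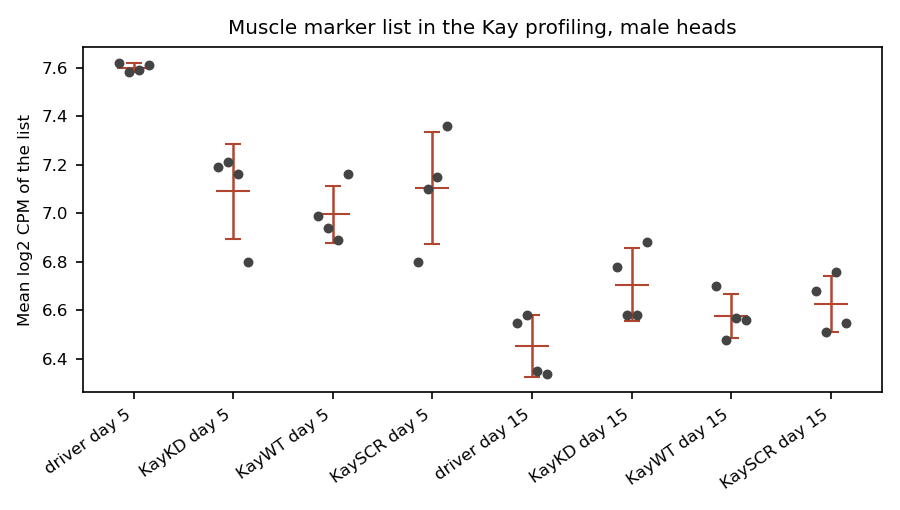
Mean log2 CPM of the muscle list in each library of the driver control, KayKD, KayWT and KaySCR at days 5 and 15. Points are libraries and bars are the mean with SD of 4; at day 5 the driver control stood at 7.6 (SD 0.0183) and the arms at 7.09 (SD 0.194), 7 (SD 0.117) and 7.1 (SD 0.231).

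At day 15 kay levels were 252 CPM (SD 42) in KayKD, 274 CPM (SD 21.1) in KayWT, 297 CPM (SD 36.4) in KaySCR and 283 CPM (SD 10.7) in the driver control. The fold changes are -0.05 (SE 0.11, p 0.916), 0.019 (SE 0.11, p 0.98) and 0.11 (SE 0.11, p 0.937). KayKD raised Pepck2, of gluconeogenesis (2R, 18527430 to 18535749), from 11.9 CPM (SD 2.69) to 127 CPM (SD 39.8; 3.54, SE 0.31, p 6.7e-09). It also raised Achl (2R, 14420324 to 14424764) by 2.74 (SE 0.4, p 5.52e-05) and CG43402 by 2.6 (SE 0.24, p 1.47e-08). The Rh1 opsin gene ninaE rose from 9620 CPM (SD 1040) to 19100 CPM (SD 6700; 1.1, SE 0.18, p 0.000493) and Rh5 by 1.26 (SE 0.25, p 0.00425). The corneal lens gene retinin fell by -1.88 (SE 0.19, p 6.01e-08) and lncRNA:cherub by -2.09 (SE 0.25, p 2.04e-06). CG11313 stood at 26 CPM (SD 8.84) against 0.0369 CPM (p 3.2e-08), and Mmp1 rose by 0.92 (SE 0.19, p 0.00917; p 0.0831 without KayKD replicate 4).

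Photoreceptor genes were higher in KayKD at day 15 (21 tested, 4 rose, 6 over the list alone, median 0.24, p 1.87e-05, 0.17 with an estimated correlation). Muscle (0 passed, 4 over the list alone, 0.29, p 0.0181, 0.17 with an estimated correlation), Imd (20 tested, 0 passed, 0.13, p 0.0397, 0.17 estimated) and autophagy genes (25 tested, 0 passed, 0.1, p 0.0404, 0.17 estimated) were higher. Oxidative phosphorylation genes (1 fell, 3 over the list alone, -0.15, p 0.0122, 0.531 with an estimated correlation) and Turandot genes (4 tested, 0 passed, 1 over the list alone, -1.2, p 0.0352, 0.476 estimated) were lower. P-values were 0.81 for the JNK pathway (0 passed), 0.409 for JNK targets (1 rose and 1 fell) and 0.409 for ER stress (0 passed, 2 over the list alone). In all, 62 genes rose and 60 fell (edgeR). That count was 59, 80, 70 or 76 without driver replicates 1 to 4 and 77 or 67 without KayKD replicate 3 or 4. Other splits gave at most 1.

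KayWT at day 15 raised Achl from 20.2 CPM (SD 1.12) to 208 CPM (SD 49.6; 3.42, SE 0.4, p 1.27e-06). It raised CG34134 by 2.9 (SE 0.31, p 2.15e-07), Rh5 by 2.55 (SE 0.24, p 2.37e-08), trpl by 0.66 (SE 0.1, p 0.000137) and the ribosomal protein gene RpL18 by 0.57 (SE 0.12, p 0.00503). CG16713 fell by -1.79 (SE 0.21, p 1.42e-06) and Lsp1beta, which rose in KayKD at day 5, by -1.56 (SE 0.33, p 0.00701). Ribosomal protein genes were higher (82 tested, 2 rose, 10 over the list alone, median 0.14, p 4.86e-11, 0.489 with an estimated correlation). So were photoreceptor (3 rose, 0.16, p 0.00231, 0.477 estimated) and oxidative phosphorylation genes (2 rose, 0.077, p 0.00945, 0.489 estimated). Antimicrobial peptides (15 tested, 0 passed, 1 over the list alone, -0.29, p 0.00945, 0.555 with an estimated correlation), heat shock (16 tested, 0 passed, -0.75, p 0.0238, 0.489 estimated), neuronal (1 fell, -0.12, p 0.0238, 0.555 estimated) and fat body genes (7 tested, 2 fell, -0.22, p 0.0238, 0.477 estimated) were lower. P-values were 0.279 for the JNK pathway (0 passed), 0.47 for JNK targets (0 passed) and 0.64 for ER stress. The marker w rose by 1.15 (SE 0.26, p 0.0146; p 0.0712 without driver replicate 3 and 0.0891 without KayWT replicate 3). In all, 89 genes rose and 56 fell (edgeR). That count was 83 or 90 without driver replicate 1 or 3 and 76 or 89 without KayWT replicate 3 or 4. Other splits gave 0.

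KaySCR at day 15 raised Achl by 3.56 (SE 0.41, p 1.12e-06), Rh5 by 3.05 (SE 0.24, p 2.98e-10), CG34134 by 2.68, CG11893 by 2.49 (SE 0.42, p 0.000594) and RpL18 by 0.59 (SE 0.12, p 0.00407). BomBc1 fell by -2.08 (SE 0.33, p 0.00028) and the neuronal capsid-like gene Arc1 from 388 CPM (SD 38.2) to 160 CPM (SD 44.6; -1.25, SE 0.17, p 2.34e-05). Antimicrobial peptides (0 of 15 passed, 4 over the list alone, median -1.7, p 2.39e-06, 0.388 with an estimated correlation) were lower. Bomanins (1 fell, 7 over the list alone, -0.41, p 0.00118, 0.456 estimated), Turandot (p 0.0079, 0.388 estimated) and heat shock genes (1 fell, 4 over the list alone, p 8.15e-05, 0.388 estimated) were lower too. Photoreceptor (4 rose, p 0.00481, 0.388 with an estimated correlation), ribosomal protein (1 rose, p 0.000226, 0.566 estimated) and muscle genes (p 0.0459, 0.388 estimated) were higher. P-values were 0.316 for the JNK pathway (0 passed), 0.33 for JNK targets (0 passed) and 0.586 for ER stress. In all, 58 genes rose and 27 fell (edgeR). That count was 56 without driver replicate 4 and 54 without KaySCR replicate 2, and other splits gave at most 2.

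By age, muscle genes differed between the arms and the driver control, higher at day 15 relative to day 5 in KayKD (p 6.27e-08, 0.0018 with an estimated correlation), KayWT (p 5.05e-12, 0.00013 estimated) and KaySCR (p 3.99e-11, 0.00019 estimated). Act57B stood at 0.99 (SE 0.15, p 0.00074), 1 (p 0.000831) and 1.09 (SE 0.15, p 9.94e-05). Achl rose by age in KayWT (4.49, SE 0.55, p 1.66e-05) and KaySCR (4.76, SE 0.55, p 4.53e-06), and CG43402 in all 3 arms (KayKD 2.32, SE 0.32, p 0.000331; KayWT 1.89, p 0.00202; KaySCR 2.71, p 4.53e-06). Lsp1beta fell in KayKD (-2.55, SE 0.46, p 0.00579) and KayWT (-2.79, SE 0.46, p 0.00202). Oxidative phosphorylation genes were higher in KayWT (p 5.97e-14, 0.0133 with an estimated correlation), in KayKD (p 2.79e-05, 0.297 estimated) and in KaySCR (p 3.44e-06, 0.218 estimated). Ribosomal protein genes were higher in KayKD (p 5.24e-05, 0.69 with an estimated correlation), KayWT (p 0.00216, 0.616 estimated) and KaySCR (p 0.00077, 0.612 estimated), and Turandot genes were lower in KayKD (p 0.00587, 0.297 estimated). In KayWT, Nrf2 (p 0.00216, 0.0951 with an estimated correlation), P450 (p 0.00216, 0.138 estimated), fat body (p 0.00983, 0.138 estimated) and lipid genes (p 0.0402, 0.271 estimated) were lower. Neuronal (p 0.00225, 0.436 with an estimated correlation), VAP-binding (p 0.00983, 0.17 estimated) and photoreceptor genes (p 0.0155, 0.379 estimated) were higher.

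In all, the age interactions gave 7 genes up and 8 down in KayKD (edgeR). Their count was 52, 8 or 37 without driver day 5 replicate 1, 3 or 4 and 9 without driver day 15 replicate 2 or 3. For KayWT 6 were up and 5 down. Those came to 48, 5 or 18 without driver day 5 replicate 1, 2 or 4 and to 7 or 6 without driver day 15 replicate 1 or 2. They came to 7 without KayWT day 5 replicate 2 and to 7 without KayWT day 15 replicate 1 or 4. For KaySCR 6 were up and 0 down. Exchanges of libraries gave up to 14, 24 and 3.

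KaySCR and KayWT differed little: at day 15 CG11893 was higher in KaySCR (2.64, SE 0.43, p 0.00172) and CG6040 lower (-1.28, SE 0.19, p 0.000623). At day 5 the citrate cycle gene Idh3b was higher (0.87, SE 0.15, p 0.018) and CG8745 lower (-1.23, SE 0.23, p 0.0364), with 3 genes higher and 4 lower in all (edgeR). None of these day 5 calls held in every fit. Lost without KayWT replicate 2 or 4 or KaySCR replicate 1, 2 or 3 is Idh3b (p 0.115, 0.0859, 0.0553, 0.0663, 0.0579). CG8745 is lost without KayWT replicate 2, 3 or 4 (p 0.115, 0.0877, 0.0906) and without any KaySCR library (p 0.0553, 0.117, 0.116, 0.0517). The counts were 0, 4 and 0 without KayWT replicates 2, 3 and 4 and 0, 0, 0 and 1 without KaySCR replicates 1 to 4. Another split also gave 7, so chance cannot be excluded. Neuronal (p 3.99e-06, 0.272 with an estimated correlation) and photoreceptor genes (p 4.43e-05, 0.272 estimated) were higher at day 5. Ribosomal protein genes (p 0.000159, 0.676 with an estimated correlation) and Bomanins (p 0.000953, 0.626 estimated) were lower. So were Nrf2 (p 0.0169) and lipid genes (p 0.0408), and VAP-binding genes were higher (p 0.0305), all 3 at 0.272 with an estimated correlation. At day 15 P450 genes were higher (p 0.00429, 0.406 with an estimated correlation). Oxidative phosphorylation (p 0.00429, 0.505 estimated), ribosomal protein (p 0.000561, 0.672 estimated) and Bomanin genes (p 0.0146, 0.672 estimated) were lower, and fat body genes were higher (p 0.0267, 0.406 estimated). Day 15 gave 8 genes higher and 4 lower. That count was 4, 5 or 5 without KayWT replicate 1, 3 or 4 and 5 or 4 without KaySCR replicate 1 or 2, and other splits gave at most 2.

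In the driver control Mlc2 was lower at day 15 than day 5 (-1.2, SE 0.11, p 2.41e-09), as were Act88F (-2.15, p 2.34e-07) and ATPsynD (-0.87, SE 0.13). CG11458 fell from 288 CPM to 2.32 CPM (-7.11, SE 0.51, p 4.27e-12). CG12256 rose by 3.51 (SE 0.42, p 5.99e-07), the lipase gene bmm by 1.38 (SE 0.17, p 8.12e-07) and Desat1 by 0.79 (p 1.95e-06). Muscle genes fell (9 of 12 fell, 12 over the list alone, median -0.97, p 1.12e-19, 2.31e-06 with an estimated correlation). So did oxidative phosphorylation genes (29 of 40 fell, 37 over the list alone, -0.58, p 4.11e-35, 4.56e-05 estimated). Lipid (7 rose and 1 fell, p 0.00012, 0.0236 estimated) and neuropeptide genes (6 rose and 1 fell, p 0.000493, 0.0383 estimated) rose. Heat shock (3 rose, p 0.00549, 0.223 estimated), P450 (3 rose, p 0.011, 0.184 estimated) and ribosomal protein genes (4 rose, p 0.00456, 0.517 estimated) were higher. So were proteasome (p 0.0425, 0.223 estimated), apoptosis and Xrp1 (2 rose, p 0.0425, 0.086 estimated) and yolk genes (p 0.0167, 0.086 estimated). Neuronal genes were lower (4 fell, 8 over the list alone, p 0.000116, 0.223 estimated). In all, 269 genes rose and 326 fell (edgeR). That count was 381 or 368 without day 5 replicate 2 or 3 and 361 or 392 without day 15 replicate 2 or 3.

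**Figure D5:**
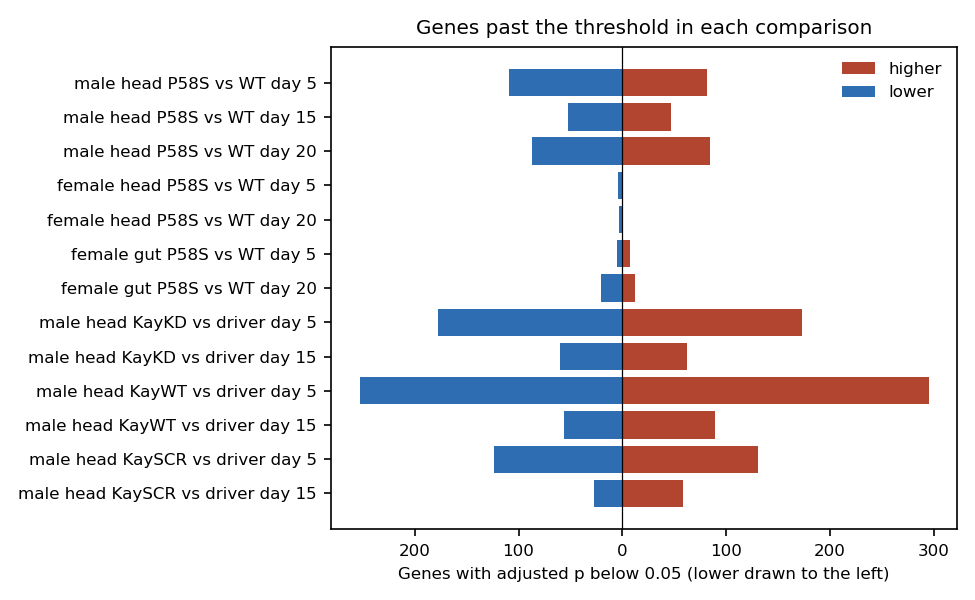
Number of genes past an adjusted p of 0.05 in each comparison of P58S with WT and of a kay arm with its driver control. Higher is drawn to the right in red and lower to the left in blue, 4 libraries per group.

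Genes changed by P58S were followed into the kay arms, which are separate libraries. The 106 tested genes lower in P58S at day 5 were higher in KayWT (median 0.21, 73.6% higher, camera p 0.0111, 0.522 with an estimated correlation) and in KaySCR (0.19, 70.8%, p 0.0111, 0.522 estimated), and in KayKD had a median of -0.0055 (p 0.792). Those lower in P58S at day 15 were lower in KayKD (51 genes, -0.21, 29.4% higher, p 0.0131, 0.522 with an estimated correlation), with medians of -0.0173 in KayWT (p 0.535) and 0.126 in KaySCR (p 0.146). The 80 higher in P58S at day 5 had a median of -0.095 in KayWT (p 0.0895). Overlaps of single genes ran in both directions. Of genes lower in P58S at day 5, 14 rose in KayWT (3.23 by chance, Fisher p 8.83e-05), 7 rose in KaySCR (1.45 by chance, p 0.00358) and 6 fell in KayKD (1.97 by chance, p 0.0373). In KayKD 3 rose (CG8012, for and Rh5, 1.9 by chance, Fisher p 0.482), and CG8012 and Rh5 rose in all arms. Of genes higher in P58S at day 5, 7 rose in KayWT (2.44 by chance, p 0.0324), 6 fell there (2.1 by chance, p 0.0419) and 4 fell in KaySCR (1.02 by chance, p 0.0419). At day 15, 3 genes higher in P58S rose in KayKD (p 0.0118) and 3 fell (p 0.0118), and 4 lower in P58S fell (p 0.002). In KaySCR 3 higher in P58S fell (p 0.002) and 3 lower in P58S rose (p 0.0118), and in KayWT no overlap passed.

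Between sexes, whole-head P58S effects had a Pearson r of 0.00567 across 9199 genes at day 5 and 0.0664 at day 20. Of genes called in male heads, 110 of 183 had the same sign in female heads at day 5 (binomial p 0.00762) and 113 of 167 at day 20 (p 5.81e-06), though genes are not independent of each other. At day 5 these were 72 of 81 higher and 38 of 102 lower in P58S males. Relative to the all-gene median the counts were 48 and 59 (p 0.0263), and 114 in all at day 20 (p 2.69e-06). The falls of to and CG34215 at day 5 (2 genes, 0.0444 by chance, Fisher p 0.00288) and of to at day 20 are shared by male and female heads. Female heads and guts share the fall of to at both ages and that of CG6006 at day 20, with an r of 0.0736 at day 5 and 0.036 at day 20 over 8343 genes.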

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

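Tests chosen after the result was seen are those on the genetic background, on the muscle covariate, on depth over the same genes, on the genotype in female heads, and on to beside the clock genes; the others were chosen before.

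The 31 genes with the same P58S change at all 3 male ages may come from the P58S change or from a genetic background that differs between the WT and P58S stocks. Depth as a cause is excluded, since 24 of the 31 kept their calls after thinning all libraries to 2477839 reads. Background linked to a few places on the chromosomes cannot be told: 5 pairs of the genes lie within 500 kb, against a median of 4 and a 95th percentile of 8 in random sets. Among transposable element insertions called at day 5, 10 of 18 were called in the same direction at all ages. That is 55.6% against 16.2% of the genes called at day 5 (Fisher p 0.000405), which is what a background difference would give. In female heads 21 of 29 had the same sign at day 5 (20 relative to the all-gene median, binomial p 0.0614), as both a P58S effect and a background carried by both sexes could give, so the 2 cannot be told apart here.

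The KayKD and KayWT arms moved the same genes the same way at day 5, although knockdown and overexpression would be thought to oppose each other: 69 genes rose and 52 fell in both (means of 12 and 8.83 with split controls), and 2 went opposite ways. Chance values of the shared driver libraries alone are excluded as the cause. The covariance of both effects was 0.362 with shared controls (mean 0.244 in simulated unchanged groups). It was 0.156 with split controls (at most 0.0481 in simulated unchanged groups). A way in which all driver libraries differ from the arms survives such a split, so it is not excluded. Thinning to 1205951 reads gave 0.172 but dropped genes to 7536 and so is void as a test. The same genes without thinning gave 0.145, so the bound written for excluding unequal depth was met. However, thinning adds counting noise to the shared controls, which by itself raises the covariance, so the test cannot exclude depth. With the muscle list as a covariate the value was 0.708, and although the bound written for excluding muscle content was met, 88.7% of the spread of the covariate lies between groups, so its slope error enters both effects and the test cannot tell. In 2 insertions the arms KayKD and KayWT differed from the driver control in the same direction at both ages (1 was at 15.1 CPM in the driver control at day 5 and at 0 in all arms), so a background shared by the arms may contribute, and the split-control value of 0.156 may measure that as well as kay.

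The clock genes were lower in P58S at day 15 and higher at day 20, which could come from collection at different times of day or from a shifted clock in P58S. Genes that peak together at dusk (per, tim, vri, Pdp1) had means of 0.0543 (SE 0.0859), -0.94 (SE 0.086) and 0.802 (SE 0.09) at days 5, 15 and 20. Clk and cry, which peak in the opposite phase, had means of -0.416 (SE 0.127) at day 5, 0.266 (SE 0.129) at day 15 and -0.48 (SE 0.131) at day 20, which fits a difference in collection time but also a phase shift of the clock, and the labels give no hour. Depth is excluded, since the means after thinning were -0.937 at day 15 and 0.848 at day 20. Other genes under clock control, such as Hr38, could be moved by the same cause, but to was lower at day 15 (-3.99, SE 0.37) and at day 20 (-6.35, SE 0.44) while the mean of the dusk genes changed sign, so this timing is not the whole cause of its fall.

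Each count was set against other splits of the compared libraries, the real one included. Of 35 splits, 2 gave at least as many genes for P58S males at day 5, KaySCR at day 5, KaySCR against KayWT at day 5 and WT age in female heads, and of 60 exchanges 6 did so for the P58S interaction to day 20. Chance cannot be excluded for any of these 5. The P58S interactions in female heads and guts have 0 genes, which 100 of 100 exchanges reach whatever the data, so these splits decide nothing (highest others 1 and 2). For KayWT by age 2 of 60 did so, and in every other comparison only 1, the real one. In the kay series at day 5 the highest other splits placed driver control replicate 1 with the arm.

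Age interactions met the rule for differences between ages for 10 genes (day 15) and 20 genes (day 20) in P58S males, 15 in KayKD, 11 in KayWT and 6 in KaySCR.

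Insertions of transposable elements, left out of the comparisons, also passed edgeR's threshold: 18, 15 and 18 in P58S males at days 5, 15 and 20, 16 and 12 in KayKD, 30 and 13 in KayWT, and 24 and 12 in KaySCR at days 5 and 15.

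Dixon's test marked 18 of 198 sets of 4 libraries over 9 measures as holding an outlier, where chance gives about 1 in 20, or 10. In male heads these were genes detected in P58S day 15 replicate 1 (10990, others 11426 to 11507) and KayKD day 5 replicate 4 (8660, others 10026 to 10158), repo in P58S day 20 replicate 2 (24.9 CPM), w in KayKD day 5 replicate 4 (11.6 CPM, others 18.1 to 18.7) and KayWT day 15 replicate 3 (31.9 CPM, others 21 to 22.6), and mean log2 CPM of antimicrobial peptides in WT day 5 replicate 1 (3.14, others 4.82 to 5.07) and KayWT day 5 replicate 1 (3.79, others 2.37 to 2.47) and of muscle genes in KayKD day 5 replicate 4 (6.8, others 7.16 to 7.21). In female heads they were Vap33 in WT day 5 replicate 4 (456 CPM, others 655 to 683), w in WT day 5 replicate 1 (1.1 CPM, others 0), repo in P58S day 20 replicate 4 (11.2 CPM, others 24.6 to 27), muscle genes in WT day 20 replicate 1 (6.02, others 6.64 to 6.7) and yolk genes in P58S day 5 replicate 3 (7.09, others 5.39 to 5.49). In guts they were kay (574 CPM, others 166 to 229), repo (0.448 CPM, others 0) and antimicrobial peptides (3.36, others 2.83 to 2.9) in P58S day 20 replicate 2, repo in WT day 5 replicate 4 (0.158 CPM) and muscle genes in WT day 5 replicate 2 (5.72, others 5.25 to 5.33).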

How the results depend on the processing

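Over 30 summary results and 17 settings, 109 of 175 values kept within 1.5 times of the reported count or within its spread and 66 moved; the cause was not tested unless given. Of 4830 values of named genes 4419 were the same, 279 weaker, 108 stronger, 23 moved and 1 reversed, and of 519 list values 263 were the same, 255 weaker and 1 reversed. The reversed ones are RpS2 in the driver control by age (-0.0426, p 0.98, with the muscle covariate) and oxidative phosphorylation in female heads at day 5 (0.513 under fry).

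DESeq2 gave 310, 151 and 257 genes for P58S males at days 5, 15 and 20, 37 and 52 for the age interactions, 529, 258 and 68 for KayKD (days 5, 15, by age), 219 and 36 for KayWT (day 15, by age), 439, 152 and 11 for KaySCR, and 32 and 31 for KaySCR against KayWT. Without a filter on low counts there were 16 genes for the interaction to day 15, 35 for KayWT by age, 11 for KaySCR by age and 28 for KaySCR against KayWT at day 5.

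A fit on the compared groups alone, with fewer samples behind the spread, gave 40, 154 and 287 genes for P58S males, 9 for the interaction to day 20, 72 and 9 for KayKD (day 5, by age), 93 for KayWT at day 5, 33 and 186 for KaySCR, 1 and 6 for KaySCR against KayWT, and 294 for the driver control by age. In females it gave 1, 19 and 26 for heads (days 5, 20, WT age) and 24 and 7 for guts (days 5, 20).

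The muscle covariate, chosen after seeing the data, gave 80, 51 and 0 genes for KayKD (days 5, 15, by age), 74 and 4 for KayWT (day 5, by age), 61 for KaySCR at day 5 and 23 for the driver control by age. As 88.7% of its spread lies between groups, these losses say little about muscle.

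Replicate numbers do not pair libraries: residuals of libraries with the same number had a mean correlation of -0.017 in male heads. The replicate block gave 4 and 6 genes for KaySCR against KayWT and 0 for female heads at day 5.

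Female heads gave, at day 5 and day 20, 16 and 6 genes when median-centred, 12 and 6 with a pseudocount of 4, and, chosen after seeing the data, 18 and 14 with edgeR on recovered reads and 8 and 25 without the 2 shallowest WT day 5 libraries. A pseudocount of 0.25 and the deposited log2 values as they are (chosen after seeing the data) each gave 1 at day 5, and no filter gave 5 at day 20. Guts gave 5, 18 and 6 genes without a filter (days 5, 20, WT age) and 21 at day 5 with edgeR on recovered reads.

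Of list tests, 173 passed camera at its preset correlation, 19 with an estimated correlation and 105 with fry. Of P58S gene sets in the kay arms, 3 passed, and 0 with an estimated correlation. The covariance of the KayKD and KayWT effects, 0.362, was 0.156 with split controls and 0.708 with the muscle covariate.

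With 1 library left out the counts ran from 91 to 365, 69 to 87 and 107 to 147 for P58S males (days 5, 15, 20), 6 to 18 and 8 to 30 for the interactions, and 709 to 953 for WT age. For KayKD they ran 172 to 629, 59 to 132 and 8 to 52 (days 5, 15, by age), for KayWT 253 to 1092, 76 to 122 and 5 to 48, for KaySCR 96 to 690, 54 to 87 and 4 to 8, for KaySCR against KayWT 0 to 6 and 4 to 16, and for the driver control 361 to 892. Female heads gave 0 to 384, 2 to 5, 0 to 0 and 56 to 460 (days 5, 20, interaction, WT age) and guts 5 to 10, 22 to 40, 0 to 1 and 7 to 49.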

Other observations

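Labels of the male genotype libraries were checked with 54 genes called in the same direction at days 15 and 20: their signed mean at day 5 was 0.434 to 0.501 in the P58S libraries and -0.63 to -0.468 in the WT libraries.

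Gene changes shared between KayKD, KayWT and KaySCR were counted at both ages. At day 5, KayWT and KaySCR shared 103 rises and 77 falls (means of 19.2 and 13.7 with split controls), and KayKD and KaySCR 53 and 47 (11 and 6.5). At day 15 KayKD and KayWT shared 17 rises and 6 falls (6.33 and 2.83 with split controls), KayKD and KaySCR 13 and 4 (4.67 and 2), and KayWT and KaySCR 44 and 18 (15.8 and 7.67).

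Genes of the yolk and ovary list in female heads had a mean log2 CPM of 7.32 (SD 0.527) in WT and 5.84 (SD 0.833) in P58S at day 5. At day 20 the means were 4.63 and 4.76.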
